A study of Mus musculus with 32 samples.

How the data were processed

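The analysis used the series matrix and array annotation as deposited, with the sample labels for genotype, age and replicate number. Values were gene-level signals that the authors deposited on the log2 scale, per the labels after robust multi-array averaging, and no unit was changed. According to the submitters' processing notes the arrays were summarised with Affymetrix Expression Console, whose version is not stated. Scanner files and scan dates were not used here, so background correction, summarisation and scan batch were not analysed here. All 32 columns of the matrix were matched to a sample, with 0 columns left over, and all mice were kept. The design, the samples, the gene lists and the alternatives named below as fixed in advance were set before the data were examined.

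Of 41345 features, 23521 named 1 gene symbol, 1814 named several and 16010 named no gene in the annotation used here. Features naming exactly 1 gene were kept, and for the 1082 genes with more than 1 feature the feature with the highest mean was used, which gave 22180 genes. No filter on low values and no pseudocount were applied. Gene symbols were matched to a RefSeq table through Entrez numbers for 21994 genes. Older symbols in the lists were matched to Ccn2, Adgre1, Jchain, C1s1, Atp5pb, Msmo1 and Epb42. List genes absent from the annotation, among them C3, Spp1 and Ren1, were not analysed here.

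Differences were estimated with limma 3.58.1 in R 4.3.3, with data.table version 1.17.8 for reading files. A single linear model held a mean for each of the 4 groups of 8 mice, with 28 residual degrees of freedom and moderated variances without trend. The 5 comparisons were KO against WT at 4 weeks, KO against WT at 7 weeks, the difference between those 2, and 7 against 4 weeks within each genotype. p values were adjusted by Benjamini-Hochberg over the 22180 genes of a comparison, and a gene passed at adjusted p below 0.05. Fold changes of at least 1.5 were counted beside it, and confidence limits were set at 95%. Differences between ages in the genotype effect were taken from the interaction test and not from comparing which genes passed.

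Genes were named by a fixed rule: Col4a3, Col4a4 and Col4a5 in every comparison, and the genes with the largest changes among those that passed, up to 10 per direction for KO against WT at each age and 6 in the other 3 comparisons. Predicted genes, small RNA genes, olfactory and vomeronasal receptors and antigen receptor segments were left out of these, by their symbols. The segment Igh-VS107 escaped this filter and is named. Within each list up to 4 members with the smallest p among those that passed, and up to 2 with the largest change among those that did not, could be named. Genes named outside this rule are said in the text to have been chosen after their values were seen.

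Gene lists were assembled from general knowledge of kidney biology, 35 lists with 642 genes, of which 583 were measured. The 34 lists with at least 5 measured members were tested with camera at its preset inter-gene correlation of 0.01 and adjusted over the 34. They were glomerular basement membrane, podocyte markers, endothelial markers, mesangial and pericyte markers, proximal tubule markers, loop of Henle markers, distal tubule and collecting duct markers, tubular injury, interstitial matrix and fibrosis, macrophage and myeloid markers, T cell markers, B cell and plasma cell markers, neutrophil markers, chemokines and cytokines, complement, interferon response, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, cell cycle, lysine deacetylases, renin-angiotensin system, p53 targets, unfolded protein response, vitamin D and phosphate handling, androgen-responsive kidney genes, circadian clock, immediate early genes, heat shock, hypoxia targets, adipocyte markers, adrenal cortex markers, urothelium markers and skeletal muscle markers. Erythroid markers were fixed as well and not tested, because 2 members were measured. Members were counted after adjustment over all genes and again after adjustment over the members of the list.

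Col4a3, Col4a4 and Col4a5 were also compared with exact permutation tests over all 12870 splits of 16 mice into 8 and 8. Per-mouse means of lists were compared in the same way and adjusted over the lists, a test added after the data were seen. Genotype differences at the 2 ages were correlated across genes by Pearson and Spearman coefficients, with a jackknife over mice, and overlaps were set beside n1 × n2 / N. Relations between list means across the 8 mice of a group were tested by permutation over all pairings and adjusted over 15 relations in 3 groups. KO mice at 7 weeks parted into 2 sets of 4 along the leading principal component, with the widest gap at 0.515 of their range. On these values the relations left out this 4th group, with none within sets of 4. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for these steps and for the figures.

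Alternatives fixed in advance were a fit of the compared groups alone, trend and robust moderation, array weights, centring of array medians, quantile normalization, a filter at a log2 mean of 5, the mean of all features per gene, all features of the array, replicate number as a block, each mouse left out in turn, exact rank-sum tests, an estimated correlation in camera, and fry. Leaving out the 2 mice with the lowest array weights together, leaving each mouse in turn out of the list tests, regression of list means on the gene length measure of the array, and the exact permutation of list means were added after the data were seen. Every feature naming Col4a3 was also to be compared, and gave no further value because 1 feature names it. Group labels were also redrawn for 100 splits per comparison, the real one included.

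The gene test was run on simulated data with the same design, in which 50 genes per size were changed among 22180. At 4 weeks 32%, 82%, 98% and 100% of genes changed by log2 0.3, 0.6, 1 and 1.5 were recovered, and 3 unchanged genes were called. At 7 weeks the shares were 34%, 82%, 96% and 98%, with 8 unchanged genes called. With 2 lists shifted by log2 0.3, camera called 2 of 2 in each comparison and 0 of 32 others that shared no gene with them. Genes were drawn independently of each other in these simulated data. The runs therefore do not show how often camera calls lists whose genes move together.

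Left out of the comparisons were features with several or no gene names, which were counted and not interpreted, and physiological measures, which are not given in the sources used here.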

Results

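Gene expression was measured in whole kidney of male Col4a3-null (KO) and littermate wild-type (WT) mice, with 8 mice of each genotype at 4 weeks and 8 of each at 7 weeks of age. Each of the 32 mice contributed 1 Affymetrix Mouse Gene 2.0 ST array, and the deposited values are gene-level log2 signals after RMA. A total of 22180 named genes entered the comparisons. The number of arrays per group limits the precision of every estimate below. Arrays of the same group correlated at 0.965 to 0.995, and the leading 2 principal components held 37.3% and 19.8% of the variance. The median standard deviation of a gene was 0.196 in WT and 0.208 in KO mice at 4 weeks, and 0.159 and 0.165 at 7 weeks. Unless stated otherwise, gene values are limma estimates of the log2 difference ± standard error with n = 8 mice per group, and p values are adjusted over the 22180 genes. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 34 lists.

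Col4a3, the targeted gene, encodes the α3 chain of the type IV collagen network of the mature glomerular basement membrane. Which part of it is deleted is not given in the sources used here, so probes over exons that remain may still give signal. At 4 weeks Col4a3 averaged 7.91 ± 0.25 (SD) in KO mice, with a range of 7.60 to 8.42, and 8.90 ± 0.29 in WT mice, with a range of 8.46 to 9.33. At 7 weeks the averages were 7.27 ± 0.34 in KO (6.97 to 7.87) and 8.92 ± 0.10 in WT mice (8.74 to 9.06). Every KO mouse lay below every WT mouse of its age, and the exact permutation p was 0.000155 at each age, the smallest possible for the 12870 splits of 8 and 8 mice. The limma differences were -0.99 ± 0.13 (1.99-fold, adjusted p = 8.75e-05) and -1.65 ± 0.13 (3.13-fold, adjusted p = 3.98e-12). Col4a4 and Col4a5 encode the partner chains of the same network. Col4a4 averaged 7.99 in KO and 8.30 in WT mice at 4 weeks (exact permutation p = 0.0182, limma -0.31 ± 0.11, adjusted p = 0.375). At 7 weeks Col4a4 fell, with means of 7.67 and 8.27 (exact permutation p = 0.000155, limma -0.60 ± 0.11, adjusted p = 3.32e-05). Col4a5 did not pass in limma at either age, with differences of 0.07 ± 0.07 at 4 weeks (exact permutation p = 0.35) and -0.13 ± 0.07 at 7 weeks (exact permutation p = 0.0401, adjusted p = 0.141).

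**Figure D1:**
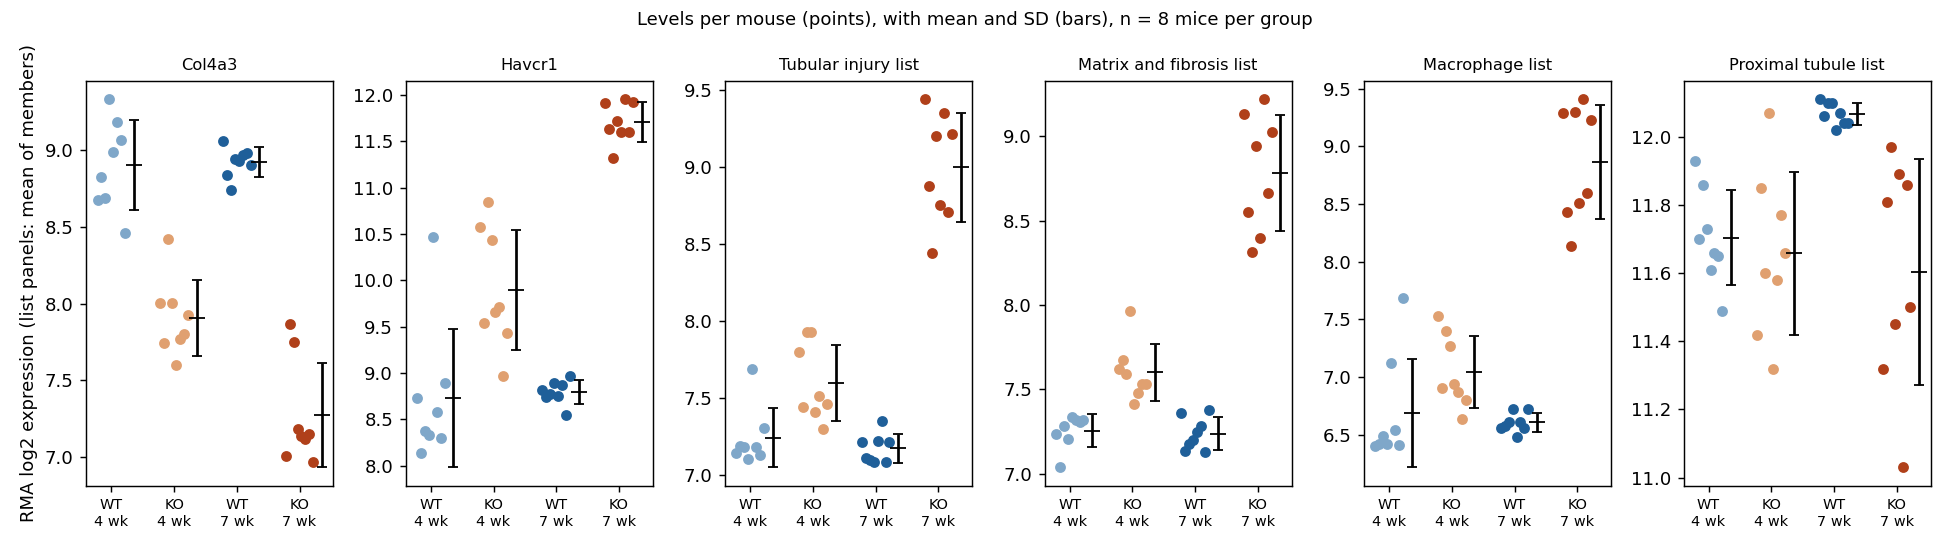
Each panel shows the log2 signal of every mouse in the 4 groups of 8, for Col4a3, for Havcr1 and for the mean of 4 gene lists, with bars for the group mean and standard deviation. Col4a3 was 7.91 in KO against 8.90 in WT mice at 4 weeks and 7.27 against 8.92 at 7 weeks.

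The comparison of KO with WT mice at 4 weeks addresses which genes differ early in the disease. Of 22180 genes, 9 passed in limma, 7 higher and 2 lower in KO mice, and 7 of the 9 changed at least 1.5-fold. Lcn2, a lipocalin secreted by injured tubule cells, rose by 1.27 ± 0.25 (2.42-fold, adjusted p = 0.0342, n = 8 per group). Mgp and Tgfbi, which encode extracellular matrix proteins, rose by 0.75 ± 0.12 (adjusted p = 0.00904) and 0.65 ± 0.12 (adjusted p = 0.0215). Plod2, a lysyl hydroxylase that modifies collagen, rose by 0.44 ± 0.08 (1.36-fold, adjusted p = 0.0236). Also higher were the stress-response regulator Nupr1 (0.69 ± 0.14, 1.62-fold, adjusted p = 0.0357), the small GTPase Rasl11a (0.63 ± 0.12, adjusted p = 0.0322) and R3hdml (0.62 ± 0.10, adjusted p = 0.00904). Besides Col4a3 (-0.99 ± 0.13), the zinc finger gene Zfp747 fell (-0.45 ± 0.09, 1.37-fold, adjusted p = 0.0455), while Col4a4 (-0.31 ± 0.11) and Col4a5 (0.07 ± 0.07) did not pass. The count depended on single mice: it was 24 without WT mouse 5, 21 without WT mouse 8, 18 without KO mouse 7, 5 without WT mouse 1 or KO mouse 5, 4 without WT mouse 4 or KO mouse 1, and 3 without WT mouse 2, WT mouse 7 or KO mouse 3. A fit of the 4-week mice alone gave 1 gene, array weights gave 5, leaving out the 2 mice with the lowest weights gave 1, and rank-sum tests gave 0, with 1603 genes below 0.05 before adjustment against 2044 in limma.

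Among the lists at 4 weeks, the matrix, cell cycle and tubular injury lists had the smallest camera p, while individual members rarely passed. Interstitial matrix and fibrosis genes include collagens, other matrix proteins, their modifiers and further fibrosis genes. This list had 0 of 31 members past the threshold over all genes, and 18 higher and 0 lower adjusted over the list alone. Their mean difference was 0.35 (camera adjusted p = 1.8e-20, adjusted p = 0.106 with an estimated correlation). The largest were the metalloproteinase inhibitor Timp1 (1.09 ± 0.25, adjusted p = 0.101 in limma) and fibronectin, Fn1 (0.82 ± 0.20, adjusted p = 0.119), neither of which passed. Of 23 tubular injury genes, Lcn2 rose and 22 did not pass, with 8 higher and 0 lower adjusted over the list alone. The injury list averaged 0.36 (camera adjusted p = 1.22e-09, adjusted p = 0.307 with an estimated correlation), and Havcr1, a tubular injury receptor, stood at 1.16 ± 0.24 (2.24-fold, adjusted p = 0.0557). Fgg, a fibrinogen chain, stood at 0.97 ± 0.24 (adjusted p = 0.116). The 31 cell cycle genes averaged 0.34 (camera adjusted p = 1.89e-14, adjusted p = 0.307 with an estimated correlation) with 8 higher and 0 lower adjusted over the list alone, among them Birc5 (0.66 ± 0.18) and Cdk1 (0.65 ± 0.23). Macrophage genes (23 members, 0 past the threshold over all genes and 0 higher and 0 lower adjusted over the list alone) averaged 0.36, with camera adjusted p = 9.36e-08 and adjusted p = 0.467 with an estimated correlation. Cd14, a myeloid receptor, and Lyz2, a lysozyme, stood at 0.76 ± 0.26 and 0.87 ± 0.30 and did not pass. Chemokine and cytokine genes averaged 0.26 (camera adjusted p = 5.7e-06, adjusted p = 0.307 with an estimated correlation), with 0 of 31 past the threshold over all genes, 2 higher and 0 lower adjusted over the list alone, and Ccl17 at 1.10 ± 0.28 and Ccl2 at 1.17 ± 0.41. Complement genes averaged 0.22 (camera adjusted p = 0.000313, adjusted p = 0.396 with an estimated correlation) with 0 of 16 past the threshold and 2 higher and 0 lower adjusted over the list alone. Immediate early genes averaged 0.14 over 17 members (camera adjusted p = 0.00114, adjusted p = 0.467 with an estimated correlation). Without KO mouse 4 the immediate early list averaged 0.08 (adjusted p = 0.0898). C7 in the complement list (0.62 ± 0.17) and Klf6 in the immediate early list (0.32 ± 0.13) did not pass.

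Distal tubule, loop of Henle, fatty acid oxidation and cholesterol synthesis lists were lower in camera at 4 weeks. The 19 distal tubule and collecting duct genes averaged -0.23 (camera adjusted p = 1.17e-07, adjusted p = 0.0462 with an estimated correlation), with 0 past the threshold over all genes and 0 higher and 2 lower adjusted over the list alone. Aqp4, a basolateral water channel, stood at -0.71 ± 0.23 (limma adjusted p = 0.329) and the anion exchanger Slc4a1 at -0.35 ± 0.17. Loop of Henle genes averaged -0.21 (camera adjusted p = 0.0102, adjusted p = 0.479 with an estimated correlation), with Slc12a1 at -0.36 ± 0.16 and Egf at -0.37 ± 0.30. KO mouse 4 had the lowest mean of this list (9.56), and without it the list averaged -0.12 (adjusted p = 0.228). Without KO mice 4 and 5 it averaged -0.11 (0.192). Fatty acid oxidation (28 genes, mean -0.08) and cholesterol synthesis (18 genes, mean -0.08, 0 higher and 1 lower adjusted over the list alone) had camera adjusted p = 0.0124 and 0.0310, and adjusted p = 0.543 and 0.467 with an estimated correlation. The fatty acid oxidation list averaged -0.03 without WT mouse 1 (adjusted p = 0.279) and -0.06 without KO mouse 1 (0.0612). The cholesterol list did not pass without KO mouse 1 (0.0853), KO mouse 4 (0.157), WT mouse 2 (0.104), WT mouse 4 (0.0634) or WT mouse 8 (0.0603), nor with array weights (0.0683) or without KO mice 4 and 5 (0.0891). Insig1, a brake on sterol synthesis, stood at -0.36 ± 0.08 (limma adjusted p = 0.102). In exact permutation tests of list means per mouse, chosen after the data were seen, matrix genes were higher (0.35 ± 0.07, adjusted p = 0.00528), with 8 KO mice above every WT mouse. Distal tubule and collecting duct genes were lower (adjusted p = 0.0211), with 6 KO mice below every WT mouse, and the other 32 lists did not pass. WT mice 5 and 8 stood apart from the other WT mice of this age: mouse 5 had the highest injury list mean (7.69), and mouse 8 the highest T cell (6.08) and interferon response list means (7.70).

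The remaining 4-week lists did not pass in camera with all mice. Proximal tubule (-0.05, adjusted p = 0.373), podocyte (0.08, 0.0612), mesangial and pericyte (0.09, 0.131) and endothelial genes (0.07, 0.131) are given as mean log2 difference and camera adjusted p. The 16 basement membrane genes averaged 0.06 (0.119), with 1 lower, Col4a3, and 4 higher and 2 lower adjusted over the list alone. The basement membrane mean ran from -0.01 without KO mouse 4 to 0.10 without KO mouse 5. B cell genes averaged 0.14 (0.0538), T cell genes 0.02 (0.835) and neutrophil genes 0.06 (0.183). Interferon response genes had a mean of -0.01 and a test in the upward direction (0.966), and so did androgen-responsive genes (-0.01, 0.835). WT mouse 8 set 2 of these values: without it T cell genes averaged 0.13 (adjusted p = 0.0250) and interferon response genes 0.14 (0.000766), and both passed. With 1 mouse left out in turn, B cell genes passed in 7 of 16 cases, podocyte genes in 6, basement membrane genes in 5, endothelial genes in 4 and circadian genes in 3. Without KO mouse 4 oxidative phosphorylation averaged 0.07 (0.0127) and proximal tubule genes -0.10 (0.0433), and without KO mouse 3 mesangial genes averaged 0.11 (0.0470). The mean turned sign for unfolded protein response genes without KO mouse 4 (-0.01), and for oxidative phosphorylation (-0.01) and proximal tubule genes (0.00) without KO mouse 5. Means within 0.02 of 0, of T cell, interferon, androgen-responsive, renin-angiotensin and urothelium genes, turned sign without any of several mice. Lysine deacetylases, the enzyme family named in the series title, averaged -0.03 (0.381), with Hdac10 at -0.27 ± 0.09 and Hdac7 at 0.22 ± 0.14. Oxidative phosphorylation (0.02, 0.401), vitamin D and phosphate handling (-0.06, 0.428), renin-angiotensin (0.00, 0.550), circadian clock (-0.08, 0.124) and hypoxia genes (-0.05, 0.373) had 0 members past the threshold. So had heat shock (0.05, 0.126), unfolded protein response (0.04, 0.332) and p53 target genes (0.03, 0.658, 1 higher and 0 lower adjusted over the list alone). Lists of tissue outside the nephron averaged 0.07 for adipocyte (0.373), -0.06 for adrenal cortex (0.389), -0.04 for skeletal muscle (0.658) and -0.00 for urothelium genes (0.966, median 0.05 with a test in the downward direction).

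**Figure D2:**
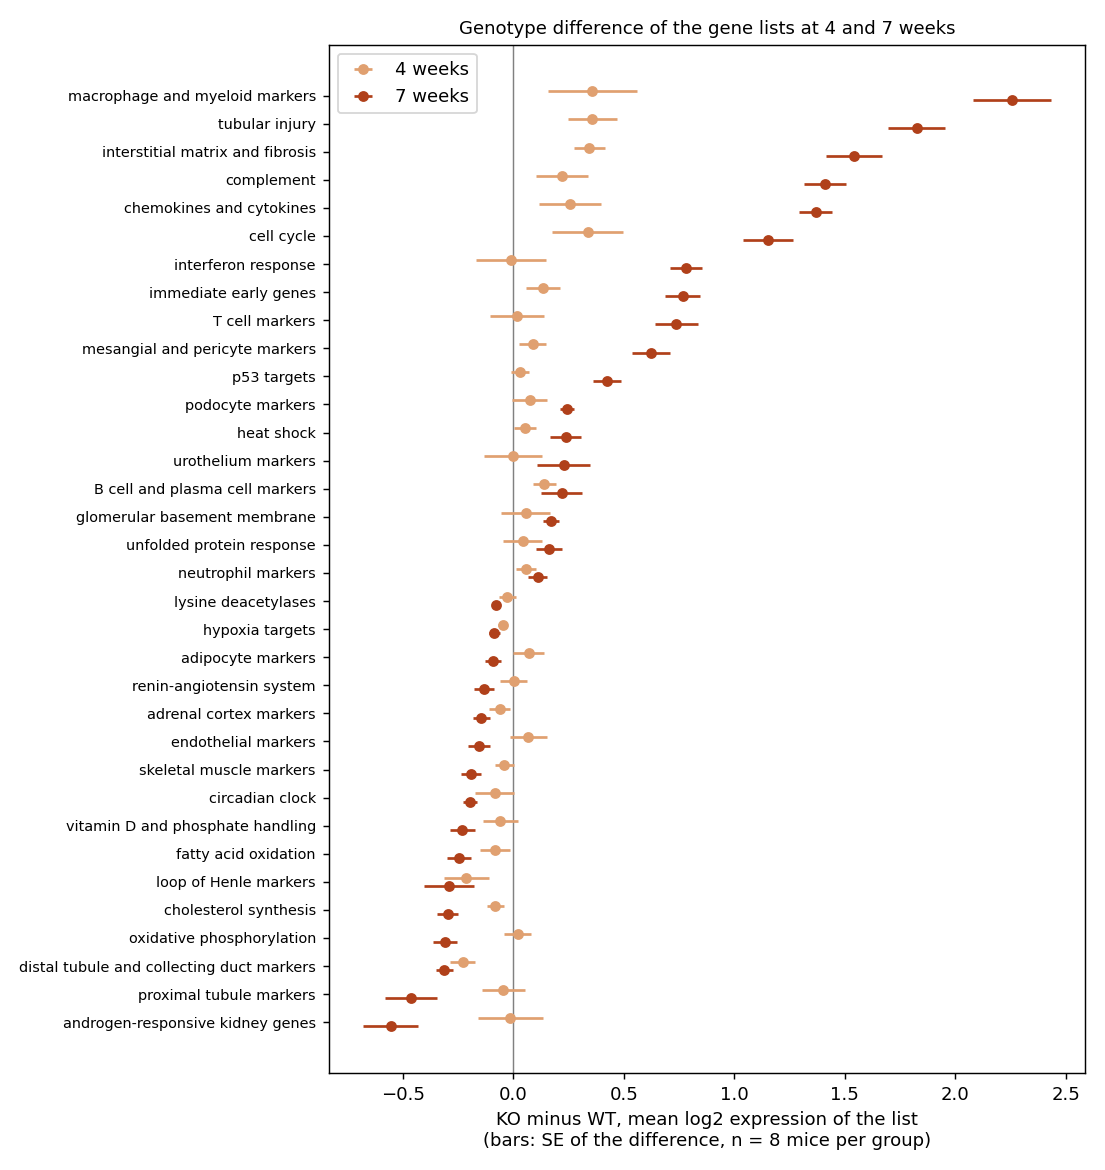
Mean log2 difference, KO minus WT, of each of the 34 gene lists at 4 and 7 weeks, with bars for the standard error over 8 mice per group. Matrix genes were at 0.35 and 1.54, and macrophage genes at 0.36 and 2.26.

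Comparing KO with WT mice at 7 weeks addresses the established disease. In limma 7167 genes passed, 32.3% of those measured, with 3469 higher and 3698 lower in KO mice. At least 1.5-fold were 1515 higher and 648 lower genes, and at least 2-fold 716 and 122. Serpina3n, an acute-phase protease inhibitor, rose by 5.15 ± 0.33 (35.5-fold, adjusted p = 1.8e-13, n = 8 per group). Chemokines for T cells and monocytes followed, with Ccl5 at 4.57 ± 0.41, Ccl2 at 4.47 ± 0.41 and Ccl17 at 4.10 ± 0.28. The adhesion molecule Vcam1 rose by 4.29 ± 0.28 (19.6-fold), the epithelial cytokine Il1f6 by 4.16 ± 0.39, the lysozyme Lyz2 by 4.07 ± 0.30 and Timp1 by 4.05 ± 0.25. Lcn2 rose by 3.81 ± 0.25 (14.1-fold) and Cd14 by 3.56 ± 0.26 (11.8-fold). Lower genes included the cytochrome Cyp2d12 (-2.76 ± 0.32, 6.78-fold, adjusted p = 3.26e-08), the carbonic anhydrase Car3 (-2.66 ± 0.36), the nuclease Dnase1 (-2.28 ± 0.31) and Hpd, an enzyme of tyrosine breakdown (-2.15 ± 0.31). Egf, a growth factor made in the thick ascending limb, fell (-2.04 ± 0.30, 4.11-fold). Also lower were the anion transporter Slc22a7 (-1.87 ± 0.36), the phosphodiesterase Pde6a (-2.01 ± 0.28), the immunoglobulin receptor Fcamr (-1.86 ± 0.33), Clec2h (-1.83 ± 0.39) and the dipeptidase Cndp1 (-1.73 ± 0.22). Col4a3 (-1.65 ± 0.13) and Col4a4 (-0.60 ± 0.11) fell, and Col4a5 (-0.13 ± 0.07) did not pass. The array medians differed by 0.114 between the genotypes, and after each array was centred on its median 10892 genes passed, 2568 higher and 8324 lower (23.6% against 48.4% higher as deposited). Centring lowers the mean of every list by the same 0.114. In camera 18 lists passed, and 6 with an estimated correlation. Exact permutation of list means per mouse, a test against no change that was chosen after the data were seen, passed for 33 of 34 lists.

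Tubular injury, matrix and macrophage lists were the strongest at 7 weeks. Each of the 23 injury genes rose (mean 1.83, camera adjusted p = 2.96e-28), and 23 did so adjusted over the list alone. Cd44, a hyaluronan receptor of regenerating tubule, rose by 3.18 ± 0.19 (9.04-fold, limma adjusted p = 7.69e-14) and Anxa2 by 1.88 ± 0.14 (3.69-fold). Matrix genes rose in 30 of 31 cases (31 higher and 0 lower adjusted over the list alone), with a list mean of 1.54 (camera adjusted p = 9.98e-37). Among them were vimentin, Vim (2.17 ± 0.13), tenascin, Tnc (3.54 ± 0.21, 11.6-fold) and the collagen Col1a2 (1.71 ± 0.11, limma adjusted p = 2.02e-13), while Eln stood at 0.21 ± 0.10 and did not pass. All 23 macrophage genes rose, adjusted over the list alone as well, with a list mean of 2.26 (camera adjusted p = 4.68e-30). Itgax, an integrin of myeloid cells, and the lysosomal marker Cd68 rose by 2.40 ± 0.16 and 2.64 ± 0.19. These 3 lists stayed past the threshold with an estimated correlation, at adjusted p = 0.00637, 0.00637 and 0.0171.

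Chemokine, complement, immediate early, interferon and T cell lists were also higher in camera at 7 weeks. Of 31 chemokine and cytokine genes 25 rose and 0 fell (26 higher and 2 lower adjusted over the list alone), with a mean of 1.37 (camera adjusted p = 8.34e-19). The monocyte attractants Ccl7 and Ccl3 rose by 2.90 ± 0.19 and 1.75 ± 0.16 and the neutrophil attractant Cxcl2 by 2.49 ± 0.19, while Ccl8 (0.27 ± 0.12) and Ccl28 (-0.43 ± 0.38) did not pass. In the complement list 14 of 16 genes rose and 1 fell (14 higher and 1 lower adjusted over the list alone), with C3ar1 at 2.78 ± 0.18, C7 at 2.29 ± 0.17 and Cfi at 1.83 ± 0.14 (list mean 1.41, camera adjusted p = 3.33e-14). Immediate early genes rose in 12 of 17 cases and fell in 1 (12 higher and 1 lower adjusted over the list alone), led by Atf3 (2.12 ± 0.14), Klf6 (1.93 ± 0.13) and Egr2 (1.60 ± 0.12), with a mean of 0.77 (camera adjusted p = 1.45e-09). Interferon response genes rose in 16 of 20 cases (16 higher and 0 lower adjusted over the list alone). Their mean was 0.78 (camera adjusted p = 3.41e-09, adjusted p = 0.114 with an estimated correlation), with examples in Irf9 (1.09 ± 0.14) and Oasl2 (1.42 ± 0.18). T cell genes rose in 11 of 14 cases (12 higher and 0 lower adjusted over the list alone). Their mean was 0.74 (camera adjusted p = 1.9e-07, adjusted p = 0.114 with an estimated correlation), with Il7r at 2.21 ± 0.20 and Cd3e at 1.22 ± 0.15. The B cell list did not pass (mean 0.22, camera adjusted p = 0.135) though 4 of 12 members rose (4 higher and 0 lower adjusted over the list alone), among them Cd79b (0.69 ± 0.14) and Jchain (1.01 ± 0.40). Nor did neutrophil genes (mean 0.11, median -0.03, camera adjusted p = 0.376), of which 4 rose and 2 fell (4 higher and 2 lower adjusted over the list alone), with Csf3r at 1.12 ± 0.11.

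At 7 weeks 30 of 31 cell cycle genes were higher in KO mice (30 higher and 0 lower adjusted over the list alone), with a mean of 1.15 (camera adjusted p = 1.21e-23, adjusted p = 0.0570 with an estimated correlation). With age the list moved by -0.61 in WT and 0.20 in KO mice. Mcm6, a helicase subunit, was higher by 1.62 ± 0.16 (limma adjusted p = 6.22e-10), and the mitotic kinase Cdk1 by 2.05 ± 0.23. p53 targets rose in 9 of 16 cases (9 higher and 0 lower adjusted over the list alone), including the cell cycle inhibitor Cdkn1a (1.83 ± 0.23, 3.57-fold) and the death receptor Tnfrsf10b (0.99 ± 0.11), with a mean of 0.42 (camera adjusted p = 6.3e-05, adjusted p = 0.0570 with an estimated correlation). Heat shock genes, 3 higher and 2 lower of 11 (4 higher and 2 lower adjusted over the list alone), averaged 0.24 (camera adjusted p = 0.376), with Hspb1 at 1.93 ± 0.21 and Hspd1 at -0.45 ± 0.08. In the unfolded protein response list 5 of 19 rose and 3 fell (7 higher and 3 lower adjusted over the list alone). Their mean was 0.16 (camera adjusted p = 0.0692), with Asns at 0.82 ± 0.10 and Xbp1 at 0.45 ± 0.10. It passed without KO mouse 7 (adjusted p = 0.0477), WT mouse 5 (0.0430) or WT mouse 6 (0.0413).

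Proximal and distal tubule, metabolic and androgen-responsive lists were lower in camera at 7 weeks. Of 24 proximal tubule genes 21 fell and 1 rose (1 higher and 22 lower adjusted over the list alone), with a mean of -0.46 (camera adjusted p = 1.59e-06, adjusted p = 0.319 with an estimated correlation). Hnf4a, a transcription factor of the proximal tubule, fell (-0.47 ± 0.08, 1.39-fold, limma adjusted p = 2.66e-05), as did the amino acid transporter Slc6a19 (-1.07 ± 0.20) and the glucose transporter Slc5a2 (-0.91 ± 0.17), while the related Slc5a1 rose (0.66 ± 0.12). Oxidative phosphorylation genes fell in 26 of 33 cases (0 higher and 29 lower adjusted over the list alone), with Ndufs1 of complex I at -0.62 ± 0.09 and Sdhc of complex II at -0.46 ± 0.07 (list mean -0.31, camera adjusted p = 4.56e-09, adjusted p = 0.203 with an estimated correlation). Fatty acid oxidation genes, 17 lower and 1 higher of 28 (1 higher and 19 lower adjusted over the list alone), averaged -0.25 (camera adjusted p = 2.27e-05, adjusted p = 0.260 with an estimated correlation). Acat1, a thiolase, and Acads, a short-chain dehydrogenase, fell (-0.96 ± 0.15 and -0.72 ± 0.11), and so did Ppargc1a, a regulator of mitochondrial genes (-0.42 ± 0.07, 1.33-fold). Cholesterol synthesis genes fell in 11 of 18 cases and rose in 1 (1 higher and 11 lower adjusted over the list alone), with Cyp51 at -1.58 ± 0.23 and Insig1 at -0.81 ± 0.08 (list mean -0.30, camera adjusted p = 0.00466, adjusted p = 0.192 with an estimated correlation). Distal tubule and collecting duct genes, 10 lower and 1 higher of 19 (1 higher and 10 lower adjusted over the list alone), averaged -0.31 (camera adjusted p = 0.0321, adjusted p = 0.319 with an estimated correlation). The distal list did not pass without KO mouse 3 (adjusted p = 0.0563), 5 (0.0514) or 7 (0.0561), nor with array medians centred (mean -0.43, 0.0989). Parvalbumin, Pvalb, fell (-1.55 ± 0.20), the calcium binder Calb1 fell (-0.90 ± 0.13) and the calcium channel Trpv5 rose (0.86 ± 0.14). Androgen-responsive genes fell in 8 of 11 cases and rose in 1 (2 higher and 9 lower adjusted over the list alone), with Cyp2d9 at -1.29 ± 0.27 and Odc1 at -0.85 ± 0.19 (list mean -0.55, camera adjusted p = 0.0321, adjusted p = 0.431 with an estimated correlation). Without KO mouse 6 the androgen list did not pass (adjusted p = 0.0520), nor with array medians centred (mean -0.67, 0.114).

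Podocyte and mesangial lists passed in camera at 7 weeks, while basement membrane, endothelial and deacetylase lists did not. Podocyte genes rose in 5 of 13 cases and fell in 1 (5 higher and 1 lower adjusted over the list alone), with a mean of 0.24 (camera adjusted p = 0.0170, adjusted p = 0.319 with an estimated correlation). The podocyte mean was 0.13 with array medians centred and 0.20 after quantile normalization, and with the low value filter the list did not pass (adjusted p = 0.0606). Cd2ap, a slit diaphragm adaptor, rose by 0.69 ± 0.08 (limma adjusted p = 8.09e-09) and the transcription factor Tcf21 by 0.87 ± 0.12, while nephrin, Nphs1, did not pass (-0.16 ± 0.14). Mesangial and pericyte genes rose in 5 of 8 cases (5 higher and 0 lower adjusted over the list alone). Their mean was 0.62 (camera adjusted p = 5.32e-05, adjusted p = 0.0570 with an estimated correlation), with Thy1 at 1.31 ± 0.16 and Des at 0.85 ± 0.09. In the basement membrane list 7 of 16 genes rose, such as Nid1 (1.03 ± 0.11) and Lama2 (0.83 ± 0.11), and 2 fell, Col4a3 and Col4a4 (8 higher and 2 lower adjusted over the list alone; mean 0.17, camera adjusted p = 0.0692, mean 0.06 with array medians centred). Endothelial genes fell in 4 of 12 cases (0 higher and 4 lower adjusted over the list alone). Their mean was -0.15 (camera adjusted p = 0.267), with the growth factor receptor Kdr at -0.75 ± 0.14. Lysine deacetylases, 2 higher and 5 lower of 18 (3 higher and 5 lower adjusted over the list alone), averaged -0.08 (camera adjusted p = 0.403). The mitochondrial Sirt3 fell (-0.77 ± 0.12, 1.71-fold, limma adjusted p = 2.35e-06), as did Sirt7 (-0.40 ± 0.06), Sirt5 (-0.25 ± 0.07) and Sirt4 (-0.28 ± 0.09), while Hdac1 (0.17 ± 0.07) and Hdac5 (-0.17 ± 0.09) did not pass.

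Further lists that did not pass in camera at 7 weeks still had members that did in limma. In the renin-angiotensin list (mean -0.13, camera adjusted p = 0.403, 1 higher and 5 lower of 11, 1 higher and 5 lower adjusted over the list alone) the hormone precursor Agt rose (0.61 ± 0.14) and the converting enzyme Ace fell (-0.69 ± 0.19). Vitamin D and phosphate genes (-0.23, 0.135, 3 higher and 8 lower of 14, 3 higher and 8 lower adjusted over the list alone) included the phosphate transporter Slc20a1 (1.08 ± 0.12) and S100g (-1.13 ± 0.17). Circadian clock genes (-0.19, 0.376, 1 higher and 5 lower of 17, 1 higher and 5 lower adjusted over the list alone) included Hlf (-0.96 ± 0.15) and Tef (-0.80 ± 0.12). Hypoxia targets (-0.09, 0.471, 2 higher and 6 lower of 16, 2 higher and 6 lower adjusted over the list alone) included Hk2 (0.76 ± 0.09) and Car9 (-0.81 ± 0.12). In the loop of Henle list (-0.29, 0.471, 1 higher and 3 lower of 8, 2 higher and 3 lower adjusted over the list alone) Egf fell and Cldn16, a tight junction protein, rose (0.56 ± 0.15). Among lists of other tissue, adipocyte genes (-0.09, 0.493, 1 higher and 1 lower of 10, 1 higher and 1 lower adjusted over the list alone) included Adipoq (-0.37 ± 0.08). Adrenal cortex genes (-0.14, 0.403, 1 lower of 9, 0 higher and 1 lower adjusted over the list alone) included Fdx1 (-0.70 ± 0.11). Skeletal muscle genes averaged -0.19 (0.448, 2 lower of 10, 0 higher and 1 lower adjusted over the list alone). Urothelium genes (mean 0.23, median -0.16, camera adjusted p = 0.823, 1 higher of 9, 1 higher and 0 lower adjusted over the list alone) included Psca, a surface antigen, which rose by 3.23 ± 0.37.

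The 7-week minus 4-week difference of the genotype differences addresses which genes changed with the disease between the ages. It passed for 3779 genes in limma, 2174 more positive and 1605 more negative at 7 weeks, of which 1284 and 507 changed at least 1.5-fold. Col4a3 was among them (-0.65 ± 0.18, adjusted p = 0.00907), while Col4a4 (-0.29 ± 0.15) and Col4a5 (-0.20 ± 0.10) did not pass. The largest increases were Serpina3n (4.11 ± 0.46, 17.2-fold, adjusted p = 3.61e-07), Ccl5 (3.49 ± 0.58), Vcam1 (3.36 ± 0.40), Ccl2 (3.30 ± 0.58), the myeloid gene Ms4a6d (3.29 ± 0.50) and Lyz2 (3.20 ± 0.43). The largest decreases were Car3 (-2.74 ± 0.51, 6.67-fold, adjusted p = 0.000281), Cyp2d12 (-2.56 ± 0.46), Pde6a (-2.15 ± 0.40), Dnase1 (-2.02 ± 0.44), Ct55 (-1.97 ± 0.41) and Clec2h (-1.95 ± 0.55). Array medians over the genes tested shifted by 0.0977. Centring on them gave 5033 genes, 1673 more positive and 3360 more negative (33.2% against 57.5% more positive as deposited).

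In the same difference, matrix genes moved up in 30 of 31 cases (30 higher and 0 lower adjusted over the list alone). Their mean was 1.20 (camera adjusted p = 1.64e-30), with Tnc at 2.86 ± 0.30 and Col3a1 at 1.69 ± 0.19. Macrophage genes did so in 23 of 23 cases (23 higher and 0 lower adjusted over the list alone, mean 1.90, camera adjusted p = 2.72e-29), and injury genes in 22 of 23 (23 higher and 0 lower adjusted over the list alone, mean 1.47, camera adjusted p = 8.81e-26). Chemokine genes moved up in 20 of 31 cases (23 higher and 0 lower adjusted over the list alone, mean 1.11, camera adjusted p = 6.37e-16), and complement genes in 12 of 16 (13 higher and 1 lower adjusted over the list alone, mean 1.19, camera adjusted p = 4e-13). These 5 lists kept adjusted p below 0.05 with an estimated correlation. Their members included Itgax (2.11 ± 0.23), Krt20, a keratin of injured epithelium (2.64 ± 0.33), Ccl7 (2.37 ± 0.27) and C3ar1 (2.57 ± 0.26). Cell cycle genes moved up in 20 of 31 cases (26 higher and 0 lower adjusted over the list alone). Their mean was 0.82 (camera adjusted p = 6.15e-15, adjusted p = 0.134 with an estimated correlation), from -0.61 in WT and 0.20 in KO mice with age. Interferon response genes moved up in 14 of 20 cases (16 higher and 0 lower adjusted over the list alone). The list mean was 0.79 (camera adjusted p = 1.63e-09, adjusted p = 0.112 with an estimated correlation), with Gbp3 at 2.08 ± 0.39. T cell genes rose in 9 of 14 cases (11 higher and 0 lower adjusted over the list alone). Here the mean was 0.72 (camera adjusted p = 7.77e-08, adjusted p = 0.112 with an estimated correlation), with Il7r at 1.80 ± 0.28. Immediate early genes moved up in 9 of 17 cases (10 higher and 0 lower adjusted over the list alone). Their mean was 0.63 (camera adjusted p = 4.46e-08, adjusted p = 0.0710 with an estimated correlation), with Atf3 at 1.84 ± 0.19. For p53 targets 7 of 16 moved up (9 higher and 0 lower adjusted over the list alone), among them Cdkn1a (1.52 ± 0.32), and the mean was 0.39 (camera adjusted p = 7.82e-05, adjusted p = 0.0747 with an estimated correlation). Mesangial and pericyte genes, with 5 of 8 up (5 higher and 0 lower adjusted over the list alone), averaged 0.54 (camera adjusted p = 0.000293, adjusted p = 0.110 with an estimated correlation). Thy1, a surface glycoprotein, stood at 1.30 ± 0.23.

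The genotype difference moved down between the ages for 6 lists, of which proximal tubule genes were the 1 tubule list. Oxidative phosphorylation had 15 of 33 genes lower (0 higher and 23 lower adjusted over the list alone) and a mean of -0.33 (camera adjusted p = 1.21e-10, adjusted p = 0.153 with an estimated correlation). Ndufs3 of complex I stood at -0.44 ± 0.08 (limma adjusted p = 0.000371). Proximal tubule genes moved down in 10 and up in 1 of 24 cases (1 higher and 14 lower adjusted over the list alone). Their mean was -0.42 (camera adjusted p = 7.24e-06, adjusted p = 0.435 with an estimated correlation), with Miox, an oxygenase of inositol, at -0.61 ± 0.15 and Gatm, an enzyme of creatine synthesis, at -0.63 ± 0.17. Fatty acid oxidation genes, 7 of 28 lower (1 higher and 13 lower adjusted over the list alone), averaged -0.16 (camera adjusted p = 0.00122, adjusted p = 0.435 with an estimated correlation), with Acads at -0.74 ± 0.16. With array medians centred the fatty acid oxidation mean was -0.26. Cholesterol synthesis genes, 6 of 18 lower (0 higher and 8 lower adjusted over the list alone), averaged -0.22 (camera adjusted p = 0.0427, adjusted p = 0.426 with an estimated correlation), with Cyp51 at -1.40 ± 0.33. With 1 mouse left out in turn the cholesterol list did not pass in 10 of 32 cases (adjusted p up to 0.0842, without WT mouse 6 at 7 weeks). With array medians centred neither the cholesterol list (0.0512) nor the androgen list (0.0725) passed. Androgen-responsive genes moved down in 4 of 11 cases (0 higher and 4 lower adjusted over the list alone), among them Odc1 (-1.05 ± 0.27). Their mean was -0.54 (camera adjusted p = 0.0234, adjusted p = 0.435 with an estimated correlation). Endothelial genes moved down in 3 of 12 cases (0 higher and 4 lower adjusted over the list alone), among them Kdr (-0.77 ± 0.20). Their mean was -0.22 (camera adjusted p = 0.0482, adjusted p = 0.566 with an estimated correlation). The endothelial list did not pass in 17 of 32 cases with 1 mouse left out (adjusted p up to 0.117, without KO mouse 2 at 4 weeks), nor with the low value filter (0.0525) or the replicate block (0.0563). The other 17 lists did not pass in camera. They included podocyte (mean 0.17, adjusted p = 0.143), basement membrane (0.11, 0.365), distal tubule (-0.08, 0.762) and vitamin D genes (-0.17, 0.251). Nor did unfolded protein response (0.12, 0.251), renin-angiotensin (-0.13, 0.310), circadian (-0.11, 0.752) and hypoxia genes (-0.04, 0.762) pass. The test ran against the mean or median for loop of Henle (mean -0.08, median 0.11, test upward, 0.762) and for urothelium genes (0.23, -0.11, upward, 0.762). It did so too for muscle (-0.15, 0.02, downward, 0.668) and deacetylase genes (-0.05, 0.00, downward, 0.702). Sirt3 (-0.65 ± 0.16) and Sirt7 (-0.50 ± 0.09) nevertheless moved down in limma. Values for the last lists were 0.18 for heat shock (0.762), 0.08 for B cell (0.668), 0.05 for neutrophil (0.750), -0.16 for adipocyte (0.310) and -0.08 for adrenal cortex genes (0.702).

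Across all 22180 genes the genotype differences at 4 and 7 weeks correlated with a Pearson r of 0.428 (jackknife standard error over mice 0.124, and 0.362 to 0.478 with 1 mouse left out) and a Spearman rho of 0.290. Of the 9 genes past the threshold at 4 weeks, 8 also passed at 7 weeks, 7 higher against 1.10 expected from the counts and 1 lower against 0.334. Lcn2 (1.27 ± 0.25 at 4 and 3.81 ± 0.25 at 7 weeks) and Tgfbi (0.65 ± 0.12 and 1.99 ± 0.12) were among the 7, and Col4a3 (-0.99 ± 0.13 and -1.65 ± 0.13) was the lower gene. Zfp747 had the same sign at both ages (-0.45 ± 0.09 and -0.03 ± 0.09) and did not pass at 7 weeks.

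**Figure D3:**
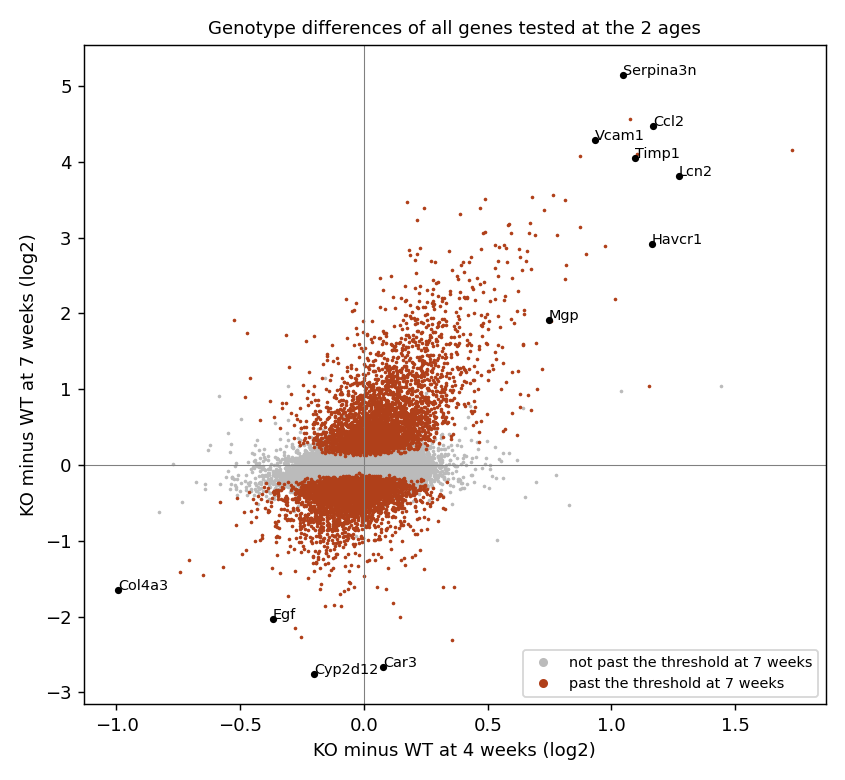
Log2 difference, KO minus WT, of every gene at 4 weeks (horizontal) and 7 weeks (vertical), with 8 mice per group and colour for genes past adjusted p of 0.05 at 7 weeks. The differences correlated at Pearson r of 0.428, and the vertical spread exceeded the horizontal.

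WT mice at 7 against 4 weeks address growth, not separated from array effects. In limma 6553 genes passed, 3417 higher and 3136 lower at 7 weeks, and 1124 changed at least 1.5-fold. Col4a3 (0.02 ± 0.13), Col4a4 (-0.03 ± 0.11) and Col4a5 (-0.14 ± 0.07) did not pass. Cyp7b1, an oxysterol hydroxylase, rose by 2.97 ± 0.43 (7.82-fold, adjusted p = 4.64e-06), the immunoglobulin genes Igh-VS107 and Jchain by 2.88 ± 0.32 and 2.64 ± 0.40, Cyp2d9 by 2.52 ± 0.27, the apolipoprotein Apob by 1.89 ± 0.27 and Azgp1 by 1.83 ± 0.22. Serpina6, the corticosteroid carrier, fell (-4.71 ± 0.40, 26.1-fold, adjusted p = 2.26e-09), as did Slc7a12 (-3.82 ± 0.34), Cyp4a14 (-3.44 ± 0.58), Cdk1 (-1.65 ± 0.23), Slc22a29 (-1.59 ± 0.27) and Esco2, a cohesin acetyltransferase (-1.52 ± 0.24). Cell cycle genes fell in 20 of 31 cases (0 higher and 21 lower adjusted over the list alone). Their mean was -0.61 (camera adjusted p = 5.42e-09, adjusted p = 0.499 with an estimated correlation), with Mcm6 at -1.13 ± 0.16. Androgen-responsive genes rose in 7 of 11 cases (9 higher and 0 lower adjusted over the list alone), with a mean of 0.95 (camera adjusted p = 7.4e-05, adjusted p = 0.423 with an estimated correlation). Proximal tubule genes rose in 12 and fell in 1 of 24 cases (14 higher and 1 lower adjusted over the list alone), with the anion transporter Slc22a8 at 0.98 ± 0.17. Their mean was 0.36 (camera adjusted p = 0.000186, adjusted p = 0.698 with an estimated correlation). Cholesterol synthesis genes rose in 10 and fell in 1 of 18 cases (11 higher and 1 lower adjusted over the list alone), such as Sqle (0.72 ± 0.10), with a mean of 0.31 (camera adjusted p = 0.000186, adjusted p = 0.423 with an estimated correlation). Distal tubule genes rose in 8 and fell in 2 of 19 cases (8 higher and 2 lower adjusted over the list alone), such as the sodium channel subunit Scnn1a (1.01 ± 0.15). The mean was 0.26 (camera adjusted p = 0.0142, adjusted p = 0.499 with an estimated correlation). Oxidative phosphorylation genes fell in 17 and rose in 4 of 33 cases (5 higher and 19 lower adjusted over the list alone), and the list averaged -0.16 (camera adjusted p = 0.0142, adjusted p = 0.756 with an estimated correlation). Basement membrane genes rose in 6 of 16 cases (7 higher and 0 lower adjusted over the list alone), such as the laminin Lamb2 (0.79 ± 0.13), with a mean of 0.28 (camera adjusted p = 0.0142, adjusted p = 0.698 with an estimated correlation). Of 18 deacetylases 8 rose and 3 fell (11 higher and 3 lower adjusted over the list alone), with Sirt7 at 0.54 ± 0.06 and Hdac6 at 0.71 ± 0.12. The deacetylase mean was 0.16 (camera adjusted p = 0.0400, adjusted p = 0.499 with an estimated correlation). Immediate early genes rose in 6 of 17 cases (6 higher and 0 lower adjusted over the list alone), such as Dusp1 (0.82 ± 0.17), and averaged 0.23 (camera adjusted p = 0.0449, adjusted p = 0.706 with an estimated correlation). Vitamin D genes rose in 8 and fell in 2 of 14 cases (9 higher and 3 lower adjusted over the list alone), among them the receptor Vdr (0.82 ± 0.15), and averaged 0.31 (camera adjusted p = 0.0472, adjusted p = 0.499 with an estimated correlation). With the low value filter the basement membrane (adjusted p = 0.0633), distal tubule (0.0624), deacetylase (0.122), vitamin D (0.132) and immediate early lists (0.132) did not pass, and with array medians centred the vitamin D list did not (0.0567). With 1 mouse left out in turn, the vitamin D list did not pass in 7 of 16 cases (adjusted p up to 0.0768, without WT mouse 1 at 7 weeks) and the immediate early list in 4 (up to 0.0824, without the same mouse). With an estimated correlation 0 lists passed in camera, with 2 below 0.05 before adjustment.

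KO mice at 7 against 4 weeks join growth, disease and any array effects. In limma 9453 genes passed, 4738 higher and 4715 lower at 7 weeks, and 2561 changed at least 1.5-fold. Col4a3 fell (-0.63 ± 0.13, adjusted p = 0.000103), as did Col4a4 (-0.31 ± 0.11) and Col4a5 (-0.34 ± 0.07). Serpina3n rose by 3.87 ± 0.33 (14.6-fold, adjusted p = 8.55e-11), Ccl5 by 3.30 ± 0.41, Igh-VS107 by 3.27 ± 0.32, the resistin-like Retnla by 3.04 ± 0.29, Jchain by 2.95 ± 0.40 and Vcam1 by 2.93 ± 0.28. Serpina6 fell (-4.31 ± 0.40, 19.8-fold, adjusted p = 5.38e-10), as did Clec2h (-2.62 ± 0.39), Spp2 (-2.15 ± 0.20), the proteoglycan Nepn (-2.04 ± 0.26), Slc22a29 (-1.91 ± 0.27) and the monocarboxylate transporter Slc16a4 (-1.82 ± 0.20). Matrix genes rose in 30 of 31 cases (30 higher and 0 lower adjusted over the list alone, mean 1.18, camera adjusted p = 9.34e-21) and injury genes in 22 of 23 (22 higher and 0 lower adjusted over the list alone, mean 1.40, camera adjusted p = 1.87e-17). Chemokine genes rose in 22 and fell in 1 of 31 cases (22 higher and 2 lower adjusted over the list alone, mean 1.07, camera adjusted p = 9.08e-11) and complement genes in 14 of 16 (14 higher and 1 lower adjusted over the list alone, mean 1.22, camera adjusted p = 1.19e-10). Immediate early genes did so in 14 of 17 (15 higher and 0 lower adjusted over the list alone, mean 0.86, camera adjusted p = 2.65e-10). These 5 lists had adjusted p = 0.0486 with an estimated correlation. Their members included Mmp2 (2.39 ± 0.19), clusterin, Clu (1.88 ± 0.13), Cx3cl1 (1.18 ± 0.09), Serping1 (1.64 ± 0.15) and Jun (1.52 ± 0.16). Macrophage genes rose in 23 of 23 cases (23 higher and 0 lower adjusted over the list alone), such as Csf1r (1.44 ± 0.13), with a mean of 1.82 (camera adjusted p = 6.52e-20, adjusted p = 0.0675 with an estimated correlation). T cell genes rose in 11 of 14 cases (11 higher and 0 lower adjusted over the list alone), such as Cd3e (1.04 ± 0.15), with a mean of 0.66 (camera adjusted p = 4.89e-05, adjusted p = 0.298 with an estimated correlation). The mesangial list had 6 of 8 genes higher (6 higher and 0 lower adjusted over the list alone) and a mean of 0.69 (camera adjusted p = 9.63e-05, adjusted p = 0.0775 with an estimated correlation). p53 targets had 12 higher and 1 lower of 16 (12 higher and 1 lower adjusted over the list alone) and a mean of 0.48 (camera adjusted p = 0.000221, adjusted p = 0.0867 with an estimated correlation). Interferon genes had 11 higher and 2 lower of 20 (12 higher and 2 lower adjusted over the list alone) and a mean of 0.57 (camera adjusted p = 0.000281, adjusted p = 0.450 with an estimated correlation). Basement membrane genes rose in 11 and fell in 3 of 16 cases (11 higher and 3 lower adjusted over the list alone), such as agrin, Agrn (1.17 ± 0.18), and averaged 0.40 (camera adjusted p = 0.00448, adjusted p = 0.450 with an estimated correlation). Podocyte genes rose in 9 and fell in 2 of 13 cases (9 higher and 2 lower adjusted over the list alone), such as Plce1 (0.91 ± 0.14), and averaged 0.35 (camera adjusted p = 0.00673, adjusted p = 0.326 with an estimated correlation). Cell cycle genes rose in 11 and fell in 1 of 31 cases (10 higher and 1 lower adjusted over the list alone), such as Mcm5 (0.79 ± 0.14), and averaged 0.20 (camera adjusted p = 0.0451, adjusted p = 0.713 with an estimated correlation). Oxidative phosphorylation genes fell in 26 of 33 cases (0 higher and 26 lower adjusted over the list alone), such as Ndufv2 (-0.79 ± 0.09), with a mean of -0.49 (camera adjusted p = 1.21e-12, adjusted p = 0.129 with an estimated correlation). Of 28 fatty acid oxidation genes 14 fell and 4 rose (4 higher and 14 lower adjusted over the list alone), with Etfa at -0.80 ± 0.09. Their mean was -0.20 (camera adjusted p = 0.0300, adjusted p = 0.666 with an estimated correlation). The cell cycle mean was 0.13 with array medians centred and 0.11 after quantile normalization, and the list did not pass with the low value filter (adjusted p = 0.203). Without KO mice 4 and 5 of 4 weeks the fatty acid oxidation list did not pass (0.0601). With 1 mouse left out in turn, the cell cycle list did not pass in 10 of 16 cases (adjusted p up to 0.136) and the fatty acid oxidation list in 4 (up to 0.0997), both highest without KO mouse 4 at 4 weeks. Centring of arrays, whose medians shifted by 0.0764, gave 11136 genes, 3906 higher and 7230 lower (35.1% against 50.1% higher as deposited).

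The age differences of the 2 genotypes correlated with a Pearson r of 0.459 and a Spearman rho of 0.478 over all genes. Higher with age in both were 2139 genes against 730 expected from the counts, lower in both 1871 against 667, and 276 passed in opposite directions. Serpina6 (-4.71 ± 0.40 in WT and -4.31 ± 0.40 in KO mice), Jchain (2.64 ± 0.40 and 2.95 ± 0.40) and Scnn1b (0.65 ± 0.11 and 1.04 ± 0.11) moved the same way in both genotypes. Mcm5, chosen after its values were seen, rose in KO mice (0.79 ± 0.14) and fell in WT mice (-0.36 ± 0.14), a difference between the genotypes that passed in limma (1.15 ± 0.19, adjusted p = 7.84e-05).

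Across mice within 3 of the 4 groups, 15 relations between list means were tested, and 2 passed after adjustment over the 15. In KO mice at 4 weeks (n = 8) the proximal tubule list moved with the podocyte list (r = 0.991, permutation p = 2.48e-05, the smallest possible, adjusted p = 0.000372, rho = 1, adjusted p = 0.000744). Without the 2 mice farthest from the median of the proximal tubule list r was 0.973 (permutation p = 0.00139). The proximal tubule and fatty acid oxidation lists also moved together (r = 0.911, permutation p = 0.00221, adjusted p = 0.0166, rho = 0.881, adjusted p = 0.0536), with r = 0.910 without 2 mice (permutation p = 0.0222). In the same mice the proximal tubule list moved with the rank correlation of gene length and the deviation of each array from its group mean (r = 0.757, permutation p = 0.0294, adjusted over 3 groups 0.0441, rho = 0.833, permutation p = 0.0154, adjusted p = 0.0231). Without 2 mice r was 0.862 (permutation p = 0.0236). WT mice at 4 weeks showed it as well (r = 0.822, permutation p = 0.0108, adjusted p = 0.0323, rho = 0.857, permutation p = 0.0107, adjusted p = 0.0231), with r = 0.575 without 2 mice (permutation p = 0.236). In WT mice at 7 weeks it did not pass (r = 0.417, permutation p = 0.313, rho = 0.381, permutation p = 0.360). After regression on this length measure, a choice made after the data were seen, the relation with the podocyte list had r = 0.981 (permutation p = 0.000149, adjusted p = 0.00223, rho = 0.976). That with the fatty acid oxidation list had r = 0.844 (permutation p = 0.00575, adjusted p = 0.0432, rho = 0.762, adjusted p = 0.184).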

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

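Except for the gene length test and the counts of redrawn splits, the tests of explanations in this part were chosen after the result was seen.

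Among list means, 15 of 136 combinations of list and group held a mouse far from the other mice of its group, and among named genes 15 of 192. About 1 in 20 groups does so by chance. By group they were 8 of 34 lists in WT and 3 of 34 in KO mice at 4 weeks, and 2 of 34 in each genotype at 7 weeks. For genes they were 8 of 48 and 4 of 48 at 4 weeks, and 3 of 48 and 0 of 48 at 7 weeks. In WT mice at 4 weeks, mouse 5 was highest for tubular injury (7.69), mouse 8 for T cell markers (6.08) and interferon response (7.70), mouse 1 for fatty acid oxidation (10.45) and hypoxia targets (8.40), and mouse 7 for urothelium markers (6.55). Mouse 2 of the same group was lowest for interstitial matrix (7.04) and mouse 6 for adrenal cortex markers (4.82). In KO mice at 4 weeks, mouse 4 was lowest for the loop of Henle (9.56), mouse 1 highest for T cell markers (5.52) and mouse 3 highest for adipocyte markers (6.20). At 7 weeks WT mouse 8 was highest for interferon response (6.59), WT mouse 6 lowest for skeletal muscle (5.29), KO mouse 3 highest for skeletal muscle (5.49) and KO mouse 6 lowest for the renin-angiotensin system (8.88).

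Among named genes, WT mouse 5 at 4 weeks was highest for Ccl17 (7.58), Cd14 (7.03), Il1f6 (8.63), Lcn2 (8.33), Mgp (11.02) and Serpina3n (7.12). WT mouse 1 was lowest for Ct55 (5.11) and WT mouse 8 for Fcamr (7.095) at that age. KO mouse 4 at 4 weeks was lowest for Slc16a4 (10.28), Slc22a7 (7.11) and Slc7a12 (9.60), and KO mouse 7 for Car3 (8.09). At 7 weeks WT mouse 3 was highest for Cyp4a14 (8.33), WT mouse 8 highest for Lyz2 (7.595) and WT mouse 1 lowest for Slc16a4 (10.49).

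Between the ages the genotype difference changed for 3779 genes in limma, and for 11 lists upward and 6 downward in camera. The named genes were Serpina3n (4.11 ± 0.46), Ccl5 (3.49 ± 0.58), Vcam1 (3.36 ± 0.40), Ccl2 (3.30 ± 0.58), Ms4a6d (3.29 ± 0.50), Lyz2 (3.20 ± 0.43), Car3 (-2.74 ± 0.51), Cyp2d12 (-2.56 ± 0.46), Pde6a (-2.15 ± 0.40), Dnase1 (-2.02 ± 0.44), Ct55 (-1.97 ± 0.41) and Clec2h (-1.95 ± 0.55). Features without a gene name were not analysed further. Of 16010, 2 passed for KO against WT at 4 weeks, 1695 at 7 weeks and 553 for the difference. By age 4472 passed in KO (980 up, 3492 down) and 3584 in WT (776 up, 2808 down). Of 1814 features naming several genes 0, 398, 177, 638 and 498 passed in the same comparisons.

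Proximal tubule markers were lower in KO mice at 7 weeks. The mean was -0.58 with array medians centred and -0.37 after quantile normalization. Both rescale deposited values and cannot exclude normalization as the cause. A smaller share of proximal tubule cells alone does not account for the lower markers, as 5 other resident cell types differed by 0.93 ± 0.10, from mesangial to distal tubule markers. Podocyte markers stood 0.71 ± 0.14 above proximal tubule markers, but whether added immune and matrix-forming cells express podocyte genes was not tested. Endothelial, loop of Henle and distal tubule markers averaged -0.15, -0.29 and -0.31, the direction that dilution by such cells gives. Dilution, lower expression per cell, a missing rise with age and loss of tubule cells amid composition shifts remain open and inseparable in whole tissue.

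Immune and injury genes were high in WT mice 5 and 8 at 4 weeks. A swapped label is argued against for mouse 5, whose Col4a3 signal was 8.99 while the highest KO mouse had 8.42 (SD of the KO group 0.25). For mouse 8, at 8.46, this test could not tell, and a wrong label stays open. A KO label would not by itself account for its pattern, since its interferon response mean of 7.70 lay 0.246 above the highest KO mouse of either age (6.84 at 4 and 7.45 at 7 weeks, larger SD 0.195). Lymphoid tissue in the sample of mouse 8 is argued against, since its B cell list stood 0.14 above the other 7 mice (SD 0.07) while its T cell list stood 0.92 above them. Infection or another illness of these mice was not tested and remains open.

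KO mice at 4 weeks were spread widely. Gene length was related to the difference between mouse 4 and mouse 5 with a Spearman rho of 0.12 over 22139 genes (99.8%), which lay between the limits set for and against a bias by length, so this test could not tell. A rise of the matrix list carried by a few mice is argued against, since 8 KO mice lay above the highest WT mouse. Stage of disease and dissection were not tested and remain open.

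When group labels were redrawn in 100 splits, the real one included, 4 splits gave at least the real 9 genes at 4 weeks, and the highest other split gave 806. That count far above 9 points to a structure among the 4-week mice other than genotype. At 7 weeks 1 of 100 splits, the real one, reached 7167 genes (highest other 5108), and 1 reached 3779 for the difference (highest other 1681). For age, 1 of 100 reached 9453 in KO (highest other 5058) and 1 reached 6553 in WT mice (highest other 2). By this measure an accident of which mice fell into which group is excluded for the comparisons at and across 7 weeks, while the 4-week share of 4 in 100 lies 1 split under the limit of 5 in 100, too close for 100 drawn splits to settle.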

How the results depend on the processing

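The number of arrays limits the precision of every count, and small and large counts both moved. At 4 weeks, where 9 genes passed in limma (7 higher, 2 lower, 7 at least 1.5-fold), a fit of the 2 groups alone gave 1 gene (0 higher, 1 lower, 1 at least 1.5-fold) with 1536 genes below 0.05 before adjustment. Array weights gave 5 (4 higher, 1 lower), and all features of the array left 1 lower. The replicate block left 1 lower gene of 7, although the replicate numbers did not pair the mice: over 48 pairs with the same number r ranged from -0.27 to 0.23, 9 exceeded 0.1 and 9 were the best match of their mouse. Exact rank-sum tests gave 0 (0 higher, 0 lower, 0 at least 1.5-fold), with 1603 genes below 0.05 before adjustment and a smallest adjusted p of 0.265. Leaving out the 2 mice with the lowest array weights (KO mice 4 and 5, weights 0.337 and 0.388), a choice made after the data were seen, gave 1 (0 higher, 1 lower, 1 at least 1.5-fold) with 1785 below 0.05 before adjustment. With each mouse left out in turn the count ran from 3 to 24, the higher genes from 2 to 20, the lower from 1 to 6 and those at least 1.5-fold from 2 to 17. The same ranges were 6310 to 7468 at 7 weeks, 3187 to 4293 for the difference, 8734 to 9984 for KO age and 5876 to 6534 for WT age. Centring of array medians gave 10892 genes at 7 weeks (8324 lower), and 3360 lower for the difference and 7230 lower for KO age. Its construction moves every gene by the shift of the medians over the genes tested. All features gave 14557 for KO age (8646 lower, 4645 at least 1.5-fold) and 10574 for WT age (6244 lower, 2956 at least 1.5-fold), with more tests by construction. Requiring 1.5-fold left 1791 of 3779 genes for the difference. Lists past the threshold in camera fell with an estimated correlation from 11 to 1 at 4 weeks, 18 to 6 at 7 weeks, 17 to 5 for the difference, 15 to 5 for KO age and 10 to 0 for WT age, where 2 lists lay below 0.05 before adjustment. Fry gave 2 lists at 4 weeks and 24 for KO age, and the low value filter gave 5 for WT age. Exact permutation of list means, chosen after the data were seen, gave 2, 33, 25 and 18 lists at 4 weeks, at 7 weeks, for KO age and for WT age. With each mouse left out in turn, a choice made after the data were seen, 10 to 16, 17 to 19, 15 to 17, 13 to 15 and 8 to 13 lists passed at 4 weeks, at 7 weeks, for the difference, for KO age and for WT age. Of the 2 relations between lists, 1 passed with z-scores and 1 without 2 mice. Where construction does not show it, the cause was not tested. Of 81 checks of the 9 genes at 4 weeks 23 lost the threshold, and 0 of 180 at 7 weeks did. Of the genes named for the largest changes, 0 reversed with centring, quantile normalization, weights or feature means. The balance turned among genes past the threshold: 57.5% moved up for the difference and 33.2% after centring, and 50.1% and 35.1% for KO age.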

Other observations

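Several lists not described above changed members with age in limma without passing in camera. In WT mice the circadian list averaged 0.28 (camera adjusted p = 0.0586), with 4 members higher and 2 lower of 17 (7 higher and 2 lower adjusted over the list alone), such as Npas2, a clock activator (0.74 ± 0.14), and Clock itself (-0.36 ± 0.09). The renin-angiotensin list averaged 0.25 (camera adjusted p = 0.0734), with the aminopeptidase Anpep higher (1.07 ± 0.19) and neprilysin, Mme, lower (-0.88 ± 0.14). Loop of Henle genes averaged -0.23 (camera adjusted p = 0.260), with the potassium channel Kcnj1 lower (-0.62 ± 0.14). Interferon response genes averaged -0.22 (camera adjusted p = 0.0680; -0.07 and 0.622 without WT mouse 8 at 4 weeks), with Ifit2 (-0.69 ± 0.11) and Rsad2 (-0.62 ± 0.11) lower. The last list passed in 6 of 16 cases with another mouse left out, the circadian list in 4 and the renin-angiotensin list in 1. Podocyte (0.19, 0.194), endothelial (0.18, 0.194), mesangial (0.15, 0.260) and hypoxia genes (0.11, 0.406) are given as mean and camera adjusted p. The injury list averaged -0.07 (0.795) and the matrix list -0.02 (0.863), with Hmox1 higher (0.82 ± 0.15) and decorin, Dcn, lower (-0.63 ± 0.12). Values for further lists were -0.08 for macrophage (0.795), -0.06 for T cell (0.680), 0.33 for B cell (0.173), -0.05 for chemokine (0.795), 0.13 for heat shock (0.397), 0.09 for unfolded protein response (0.481), 0.01 for neutrophil (0.863), -0.06 for adrenal cortex (0.727) and -0.17 for urothelium genes (0.863). Without WT mouse 8 at 4 weeks the means were 0.06 for macrophage, 0.05 for T cell and 0.03 for chemokine genes, and without WT mouse 7 -0.06 for urothelium genes. Sign differed between mean or median and test for complement (0.03, median -0.01, upward, 0.848), p53 targets (0.09, median -0.03, upward, 0.795), fatty acid oxidation (-0.04, upward, 0.795), muscle (-0.01, upward, 0.929) and adipocyte genes (mean -0.00, upward, 0.863).

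In KO mice between 4 and 7 weeks, distal tubule genes averaged 0.18 (camera adjusted p = 0.0871), with Scnn1b higher (1.04 ± 0.11) and Calb1 lower (-1.06 ± 0.13) in limma. Lysine deacetylases averaged 0.11 (0.182), with 8 higher and 4 lower of 18 (9 higher and 4 lower adjusted over the list alone), among them Hdac6 (0.67 ± 0.12), Sirt6 (0.53 ± 0.09) and Sirt3 (-0.79 ± 0.12). B cell genes averaged 0.41 (0.0871), unfolded protein response genes 0.20 (0.0893), androgen-responsive genes 0.40 (0.217) and cholesterol synthesis genes 0.09 (0.231). The unfolded protein response list passed without KO mouse 3 (0.0395) or KO mouse 4 (0.0386) at 4 weeks. Sterol genes moved both ways, with Sqle at 0.90 ± 0.10 and Cyp51 at -1.33 ± 0.23. The loop of Henle list averaged -0.31 (0.501), with Egf at -1.67 ± 0.30. Circadian (0.17, 0.349), hypoxia (0.07), vitamin D (0.14) and endothelial genes (-0.04, 0.582) did not pass in camera. Sign differed between mean and median for heat shock (0.31, -0.02, 0.454), proximal tubule (-0.06, 0.01, 0.582), renin-angiotensin (0.12, -0.06, 0.665), neutrophil (0.06, -0.03, 0.658) and urothelium genes (0.06, -0.17, 0.881). Adipocyte, adrenal cortex and muscle genes averaged -0.16 (0.501), -0.15 (0.454) and -0.17 (0.665).

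KO mice at 7 weeks lay in 2 sets of 4 along the leading principal component, with mice 2, 3, 5 and 7 between 24.5 and 36.7 and mice 1, 4, 6 and 8 between 56.4 and 62.7. Proximal tubule means were 11.81 to 11.97 in the former and 11.03 to 11.50 in the latter set. Injury means were 8.44 to 8.88 and 9.20 to 9.44, matrix means 8.31 to 8.66 and 8.94 to 9.22, and macrophage means 8.14 to 8.59 and 9.23 to 9.41. Of the 6 lists examined for gaps, 2 did not part the same mice: the widest gap set mice 4, 6 and 8 apart for fatty acid oxidation (9.59 to 9.71, others 9.85 to 9.94) and mice 3, 4 and 5 for podocyte genes (8.39 to 8.51, others 8.54 to 8.64). These values were set side by side after they were seen and no test was run on sets of 4.

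The following genes were chosen after their values were seen. In WT mouse 8 at 4 weeks the interferon-inducible GTPases Iigp1 (12.86, other WT mice 6.53), Gbp10 (12.21 and 6.25), Igtp (11.49 and 6.76) and Irgm2 (11.30 and 7.59) were high, as were the chemokine Cxcl9 (11.48 and 5.78), the proteasome gene Psmb9 (9.78 and 5.82) and H2-Eb2 (8.89 and 5.03). The highest KO mouse at 7 weeks reached 9.35 for Iigp1, 7.52 for Gbp10, 9.21 for Cxcl9 and 9.46 for Irgm2. WT mouse 5 had high Havcr1 (10.47, others 8.48), Ccl2 (9.53 and 6.39), Vcam1 (8.98 and 7.31), Il1f6 (8.63 and 5.15), Ccl17 (7.58 and 5.52) and Fgg (7.31 and 5.49). Without mouse 5 or mouse 8 the 4-week mean difference of macrophage genes was 0.42 or 0.50, of chemokines 0.32 or 0.34 and of complement 0.26 or 0.30.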
